A study of Mus musculus with 8 samples.

How the data were processed

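Acetylation of histone H3 at lysine 9 (H3K9ac), a mark of active promoters, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in cerebella of C57BL/6 mice aged 9 weeks. There were 4 libraries from heterozygous knock-in mice labelled with 266 glutamines and 4 from wild type mice. Per the labels' protocols, tissue was fixed in formaldehyde, sonicated and precipitated on magnetic beads, and libraries were sequenced single-ended. Groups and replicate numbers were taken from the sample titles. The labels do not say that replicates came from separate animals, so p-values measure the spread between these libraries, which may be technical.

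The deposited file of each library was a peak list with the start, end and score of each peak. Per the submitters' processing notes, Bowtie2 was used and the build was mm10. Peaks were called with MACS in Galaxy, separately for each library, per the file headers. The version of MACS, its settings and whether an input control was used are not given in the sources used here. The deposited score was the authors' own value per peak. Its scale was inferred from its minimum of about 50 in every list, as a transformed p-value from the peak caller, and was not stated. The score was used only to rank peaks within a list. A list holds no read counts, so the depth of each library is unknown. Exact Clopper-Pearson 95% intervals are given for shares of peaks, and they cover counting error only. A stronger antibody reaction or deeper sequencing gives a longer list, so the lists of different libraries are not on one scale. Of all 52676 peaks, 15 had a start below 0, which was set to 0.

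Gene positions came from a RefSeq gene table of GRCm38.p6, the assembly that mm10 names, which held 21887 protein-coding genes placed on the nuclear chromosomes. The design fixed before the data were examined called for windows around annotated start sites. The table gave the ends of each gene but no strand, so the window was set at 1 kb on each side of either gene end. Such a window can hold the peak of a neighbouring gene and misses internal start sites. Of the 414 distinct genes in 19 lists fixed before the data were examined, 413 matched a protein-coding gene.

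Peaks of all libraries that overlapped were merged into 19505 regions, and a library held a region if one of its peaks overlapped it by 1 bp or more. Pairs of lists were compared by the Jaccard index of base pairs and by the share of the shorter list's peaks that overlapped the longer list. Library values were compared by a two-sided exact permutation test over all 70 assignments of 4 libraries against 4, which cannot give a p below 0.0286. Within-genotype and between-genotype overlap were compared over the 35 splits of the libraries. Per region and per gene, a two-sided conditional exact test took the number of libraries with a peak as given and compared the number that were knock-in with what library-specific detection odds allow. The odds were fitted by a Rasch model over all regions or genes. Features held by 1 to 7 libraries were tested, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fisher's exact test, which ignores list length, was the alternative. With 4 libraries against 4 its p cannot fall below 0.0286. Only a feature in all 4 libraries of one genotype and none of the other has a p under 0.05. For each gene list, the log2 odds of a peak among members against all other genes, with 0.5 added to each cell, were compared by the same exact permutation test and adjusted over the 19 lists. At the smallest p that 4 against 4 allow, at least 11 lists would have to reach it together for any to pass.

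The conditional test was tested on simulated data made with the odds of these libraries, with 200 features set to be present in all libraries of one genotype and none of the other. Over 9826 gene-end windows it called 100% of these and 1 unchanged window. Over 19438 merged regions it called 0%, because the p of such a region was 0.00371 or 0.000911, depending on the genotype. At that number of changed regions a count of 0 called regions is therefore what this test gives. The changed gene-end windows all had a peak in replicate 4 of 1 genotype, whose real lists had one at only 196 genes in knock-in and 319 in wild type. No gene in the real data was in all 4 libraries of 1 genotype and none of the other. The 100% therefore does not extend to smaller changes.

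The text names Atxn7, Kat2a and Usp22 first. It then names up to 3 members of each list with the largest difference between genotypes in the number of libraries with a peak, if at least 2, with ties broken by the smaller p and then by the alphabet. Where no member differed by 2 libraries, up to 2 members detected in the most libraries were taken. It also names the 8 genes in each direction with the smallest p over all genes, with ties broken by the larger difference and then by the alphabet. Not every gene that this rule gives is named. Names chosen in any other way are marked as chosen after their values were seen.

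Alternatives set before the data were examined left out each library in turn, used the replicate number as a block, took the 1266 strongest peaks of each library, kept autosomes only, required reciprocal overlap, merged peaks within 500 bp, used windows of 500 bp or 3 kb, dropped the logarithm for gene lists, used Fisher's exact test, or changed how many libraries a restricted region needs. Chosen after seeing the data were the use of replicates 1 and 2 only, of replicates 3 and 4 only, windows over the whole gene body, and the comparisons of gene-end windows among replicates 1 and 2. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.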

Results

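H3K9ac peaks were listed for 8 cerebellar libraries, 4 from mice carrying one Atxn7 allele with an expanded glutamine tract and 4 from wild type mice. Atxn7 encodes ataxin-7, a subunit of the SAGA histone acetyltransferase complex, and its expansion causes spinocerebellar ataxia type 7 (SCA7). The series compares symptomatic knock-in mice with littermates to ask how this acetylation mark differs in the cerebellum. The lists held 10607, 11268, 5571 and 1266 peaks in knock-in replicates 1 to 4, and 11409, 7735, 3249 and 1571 in wild type replicates 1 to 4. Read depth is not given in the sources used here.

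In both genotypes the cerebellar peak lists fell into a pair of long lists of broad peaks and a pair of short lists of narrow peaks. The median peak width was 1246 and 1144 bp in knock-in replicates 1 and 2, against 148 and 132 bp in replicates 3 and 4. In wild type it was 1118 and 1065 bp against 147 and 134 bp. Peaks covered 9.09 to 14.5 Mb in replicates 1 and 2 and 0.236 to 0.991 Mb in replicates 3 and 4. For this reason values within replicates 1 and 2 are given beside the pooled ones.

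The genotypes did not differ in the size of the peak lists beyond the spread between libraries. Knock-in lists held 7178 ± 4691 peaks (SD, n = 4) and wild type lists 5991 ± 4452 (SD, n = 4), with a two-sided exact permutation p of 0.743. Covered length was 7.54 ± 8.00 Mb (SD, n = 4) against 6.05 ± 6.82 Mb (SD, n = 4), with an exact permutation p of 0.629. Median width was 667.5 ± 611 bp (SD, n = 4) against 616 ± 549.5 bp (SD, n = 4), with an exact permutation p of 0.600. Within replicates 1 and 2 the mean number of peaks was 10938 in knock-in and 9572 in wild type, and the mean covered length was 14.5 and 11.7 Mb. With 2 libraries against 2 an exact permutation test cannot give a p below 0.333.

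**Figure D1:**
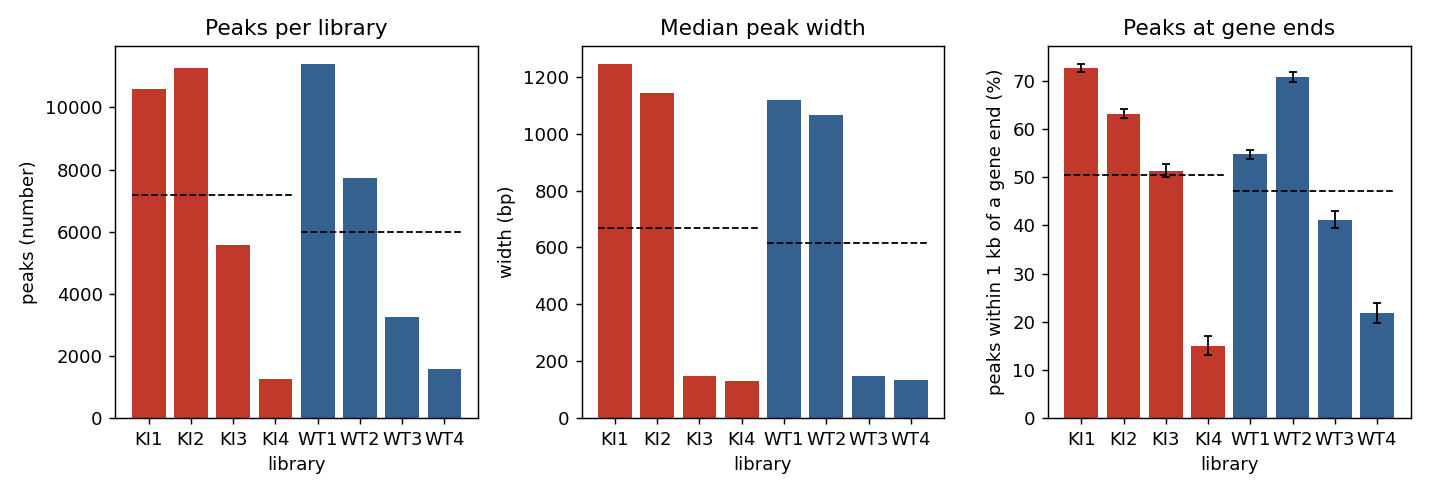
Number of peaks, median peak width in bp and percent of peaks within 1 kb of a gene end, for knock-in (KI, red) and wild type (WT, blue) libraries by replicate number. Dashed lines are group means and error bars in the right panel are exact 95% intervals. Median widths lie between 1065 and 1246 bp in replicates 1 and 2 and between 132 and 148 bp in replicates 3 and 4 of both genotypes.

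Most peaks of replicates 1 and 2 lay at the ends of protein-coding genes. The share was 72.7% in knock-in replicate 1 (exact 95% interval 71.8 to 73.5) and 63.2% in knock-in replicate 2 (62.3 to 64.0). It was 54.7% in wild type replicate 1 (53.8 to 55.7) and 70.7% in wild type replicate 2 (69.7 to 71.7). In knock-in replicates 3 and 4 it was 51.4% (50.0 to 52.7) and 14.9% (13.01 to 17.01), and in wild type replicates 3 and 4 it was 41.2% (39.5 to 42.9) and 21.8% (19.8 to 24.0). The mean was 50.5 ± 25.3% (SD, n = 4) in knock-in and 47.1 ± 20.7% (SD, n = 4) in wild type, with an exact permutation p of 0.8286. Within replicates 1 and 2 the means were 67.9% and 62.7%. Peaks outside genes made up 24.2 ± 21.3% (SD, n = 4) of knock-in lists and 25.6 ± 17.1% (SD, n = 4) of wild type lists, with an exact permutation p of 0.886.

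No difference in overlap between lists of one genotype and lists of different genotypes was detected. The mean Jaccard index was 0.120 over 12 pairs within a genotype and 0.171 over 16 pairs between genotypes, with an exact permutation p of 0.4 over 35 splits. The share of the shorter list found in the longer was 57.1% within and 56.4% between genotypes, with an exact permutation p of 0.600. Among replicates 1 and 2 the index was 0.496 within and 0.475 between genotypes. Among replicates 3 and 4 it was 0.112 within and 0.152 between genotypes, and for pairs of one library from each set it was 0.0280 and 0.0284. Such pairs were 8 of the 12 within and 8 of the 16 between genotypes, so the pooled means differ in their mix of sets, which the test does not take into account.

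**Figure D2:**
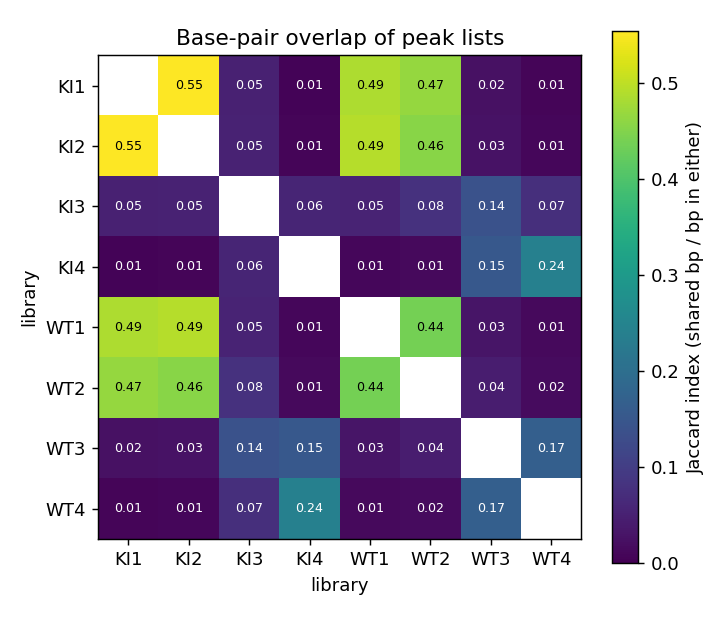
Jaccard index of base pairs for each pair of peak lists, from knock-in (KI) and wild type (WT) replicates 1 to 4. The pairs among replicates 1 and 2 of either genotype lie between 0.439 and 0.554, and pairs that join one of these with replicate 3 or 4 lie at or below 0.0789.

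Few regions were held by several libraries of one genotype and by none of the other. Of the 19505 merged regions, 39 were held by 3 knock-in libraries and no wild type library, and 40 by 3 wild type libraries and no knock-in library. None was held by all 4 of one genotype alone. Of the 39, 33 lay in or within 1 kb of a protein-coding gene, and of the 40, 19 did. By pattern, 29 of the knock-in regions were in replicates 1, 2 and 3, and 21 of the wild type regions were in replicates 1, 3 and 4. Within replicates 1 and 2, 898 regions were held by both knock-in and neither wild type library, and 174 the reverse. Other splits of the libraries gave more regions than these 79, as the closing part shows. Single libraries moved these counts, but leaving one out also changed the rule. The genotype of the library left out then needed a peak in all of its remaining libraries, which favours a lower count. The other genotype needed fewer libraries without a peak, which favours a higher count. Knock-in regions numbered 5, 1 and 4 without knock-in replicates 1, 2 and 3, and 119 and 68 without wild type replicates 1 and 2. Wild type regions numbered 0, 21, 7 and 12 without wild type replicates 1 to 4, and 77 and 62 without knock-in replicates 2 and 4.

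No merged region was called as detected more often in either genotype. The conditional exact test gave 0 calls among 19438 tested regions, 53 regions with an unadjusted p under 0.05 and 0 calls with Fisher's exact test. The smallest p by Fisher's exact test was 0.143 before adjustment, so its 0 calls carry no information of their own. The smallest conditional exact p was 0.0113. On simulated data with 200 changed regions this test called none of them, so the count sets no limit on changes of that number.

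At gene ends, 9851 of 21887 protein-coding genes had a peak in at least 1 library and 25 had one in all 8. Knock-in libraries 1 to 4 had a peak at 8565, 7927, 2276 and 196 genes, and wild type libraries at 6977, 6076, 1188 and 319 genes. The share of genes was 21.7 ± 18.9% (SD, n = 4) in knock-in and 16.6 ± 15.4% (SD, n = 4) in wild type, with an exact permutation p of 0.600. Within replicates 1 and 2 it was 37.7% and 29.8%. The conditional exact test called 0 of 9826 genes, with 90 at an unadjusted p under 0.05 and 0 calls by Fisher's exact test. The smallest p by Fisher's exact test was 0.143 here too, so it could call no gene. Without wild type replicate 2 the conditional exact test called 1 gene, Lrrc74b. The simulation tried only changes of all 4 libraries against none, so 0 calls set no limit on smaller changes.

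Atxn7 itself carried a peak at its end on chromosome 14 (gene at 13961283 to 14107316, build mm10) in replicates 1 and 2 of both genotypes and in none of replicates 3 and 4. The peak was 1975 and 1408 bp wide in knock-in replicates 1 and 2 and 1740 and 1700 bp in wild type. It also overlapped the window of the neighbouring gene Thoc7. Kat2a, the acetyltransferase of SAGA (chromosome 11, 100704746 to 100712485), had a peak in 2 knock-in and 3 wild type libraries, with a conditional exact p of 0.222. Usp22, the deubiquitinase of SAGA (chromosome 11, 61151781 to 61175059), had one in 3 libraries of each genotype.

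**Figure D3:**
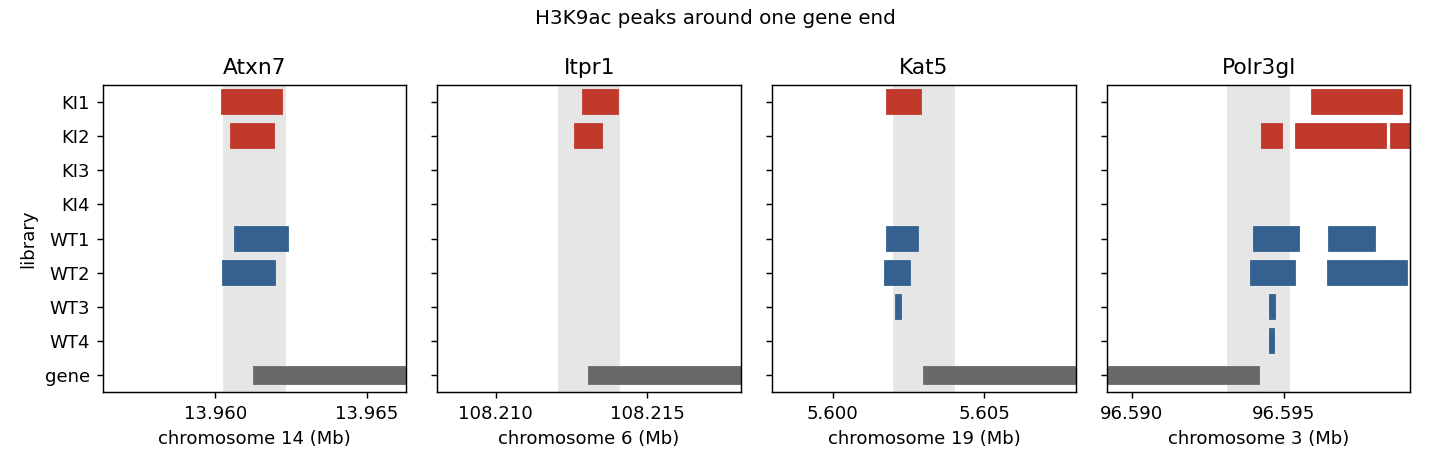
Peaks of each knock-in (KI, red) and wild type (WT, blue) library within 5000 bp of one gene end of Atxn7, Itpr1, Kat5 and Polr3gl, with position in Mb on the x axis, the 1 kb window in light grey and the gene in dark grey. Atxn7 has a peak in 2 libraries of each genotype, and Itpr1 has one in 2 knock-in libraries and no wild type library.

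Genes with the smallest p over all genes did not pass the adjustment. Polr3gl, which encodes an RNA polymerase III subunit (chromosome 3, 96577872 to 96594181), had a peak in 1 knock-in and 4 wild type libraries, with a conditional exact p of 8.4e-05 and an adjusted p of 0.743. Its peak overlapped the window of Ankrd34a. Knock-in replicate 1 had a peak at 96595923 to 96598907, just beyond the 1 kb window of Polr3gl, which a window of 3 kb would count. Lrrc74b (chromosome 16, 17544465 to 17561328) had one in 0 knock-in and 3 wild type libraries, with a conditional exact p of 0.000151 and an adjusted p of 0.743. Its adjusted conditional exact p was 0.00461 without wild type replicate 2, and 0.690 to 1.00 under the other alternatives that gave one. With a window of 500 bp it had no peak in any library. Copg2, Id4, Kat5, Mideas, Ptpn13 and Rnaseh2c, the first by the alphabet of 8 tied genes, each had a peak in 1 knock-in and 3 wild type libraries, with a conditional exact p of 0.0033. In the other direction, 24 genes had a peak in 3 knock-in and 0 wild type libraries, with a conditional exact p of 0.00948. The first by the alphabet were 1110032A03Rik, A330070K13Rik, Abcf1, Chac1, Cnpy4, Duxf3, Ercc5 and Fdxacb1. The genes 1110032A03Rik and Fdxacb1 shared one peak, and Duxf3 belongs to a multicopy family whose reads are uncertain. Peaks of Copg2, Mideas, Cnpy4 and Duxf3 also overlapped the windows of other genes.

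Gene lists for cerebellar cell types had the most peaks at granule and Purkinje cell markers in both genotypes. Of 24 granule cell markers, 22 and 21 had a peak in knock-in replicates 1 and 2, and 20 and 18 in wild type replicates 1 and 2. Of 27 Purkinje cell markers, the counts were 15 and 16 in knock-in and 12 and 11 in wild type. Of 15 markers of inhibitory interneurons they were 3 and 4 against 3 and 2. Astrocyte and Bergmann glia markers had 3 and 3 of 18 against 2 and 1, oligodendrocyte markers 4 and 3 of 20 against 2 and 1, microglia markers 1 and 0 of 17 against 0 and 0, and vascular markers 1 and 1 of 13 against 1 and 1. Lists for other tissues were near the floor, with photoreceptor genes at 3 and 1 of 20 against 1 and 0 and liver and muscle genes at 2 and 1 of 20 against 1 and 1. Over all 4 libraries the mean share of granule markers was 56.2 ± 41.5% (SD, n = 4) in knock-in and 47.9 ± 36.2% (SD, n = 4) in wild type. For Purkinje markers it was 30.6 ± 31.2% (SD, n = 4) against 23.1 ± 22.7% (SD, n = 4). Both lists had an exact permutation p of 0.771 and an adjusted p of 0.971.

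Among Purkinje cell markers, Homer3 and Itpr1 had a peak in both knock-in libraries of replicates 1 and 2 and in no wild type library. Itpr1 encodes the inositol trisphosphate receptor of the endoplasmic reticulum. The conditional exact p of each was 0.501. The peaks of Itpr1 were weak within the lists, at score percentiles 29.4 and 4.67 in knock-in replicates 1 and 2. Of the granule markers, Chn2 had a peak in 3 knock-in and 4 wild type libraries and Reln in 4 and 3. Cdh22 and Lgi2 of the interneuron list, Slc1a2 and Fa2h of the glial lists and Slc2a1 of the vascular list were found equally often in both genotypes. Glul and Mbp were in 2 knock-in and 1 wild type libraries, Kdr in 1 knock-in library, and Aif1 in none.

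Calcium handling genes had 25 and 24 of 36 members with a peak in knock-in replicates 1 and 2 and 20 and 21 in wild type. Over all libraries 11 members were found in more knock-in libraries, 3 in more wild type libraries and 13 equally often. Over all genes, 4727 were found in more knock-in and 1144 in more wild type libraries. Plcb3, a phospholipase C (chromosome 19, 6953708 to 6975006), had a peak in 3 knock-in and 0 wild type libraries, with a conditional exact p of 0.00948. That peak overlapped the window of Ppp1r14b. Cacna2d2, a calcium channel subunit, was in 4 knock-in and 2 wild type libraries, with a conditional exact p of 0.0907. Spinocerebellar ataxia genes had 24 and 21 of 31 measured members in knock-in and 19 and 17 in wild type. Eef2, which encodes the elongation factor 2, was in both knock-in libraries of replicates 1 and 2 and no wild type library. Its conditional exact p was 0.501.

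SAGA and ATAC complex subunits had 25 and 25 of 31 members with a peak in knock-in replicates 1 and 2 and 24 and 22 in wild type. Atxn7l3, an adaptor of the deubiquitinase module, was in 4 knock-in and 2 wild type libraries, with a conditional exact p of 0.0907. Peaks of Atxn7l3 also overlapped the window of Gm33851. Mbip was in 2 and 0, with a conditional exact p of 0.501. Of the other histone acetylation enzymes, 13 and 10 of 19 had a peak in knock-in and 11 and 11 in wild type. Kat5, the acetyltransferase of the NuA4 complex (chromosome 19, 5603014 to 5611556), was in 1 knock-in and 3 wild type libraries. Its conditional exact p was 0.0033, which passed when adjusted over the list alone (adjusted p = 0.0429) and gave 1.00 over all genes. The peaks lay over the neighbouring gene Rnaseh2c, reached into the window of Kat5 without reaching Kat5 itself, and counted for both genes. Adjusted over the list alone, the exact p of Kat5 was 1.00 without knock-in replicate 2 or wild type replicate 3, 0.0737 without knock-in replicate 3 and 0.0553 without wild type replicate 2. It was 0.464 with the replicate number as a block, 0.0810 with a window of 3 kb, and 1.00 with a window of 500 bp, with lists of equal length or by Fisher's exact test. By Fisher's exact test any gene in 1 against 3 libraries has a p of 0.486, so that alternative could not pass Kat5. With windows of 1 kb at the gene ends and all libraries it was the 1 list member that passed over the list alone, and 0 members of any list passed over all genes.

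Immediate early genes respond to neuronal activity. Of 20 members, 18 and 15 had a peak in knock-in replicates 1 and 2, against 13 and 13 in wild type. Fosb, Junb and Klf4 were in both of these knock-in libraries and no wild type library. Of the 15 members in both knock-in libraries these were 3, against 1.56 expected from all genes. The one-sided exact hypergeometric p was 0.199 and the adjusted p 0.949, in a comparison chosen after seeing the data. For genes of matched score 1.82 were expected, with a one-sided permutation p of 0.254. Score percentiles were 7.23 and 24.7 for Fosb, 52.1 and 0.683 for Junb and 38.2 and 37.0 for Klf4. Heat shock and unfolded protein response genes had 14 and 13 of 18 against 11 and 9, and Hspa5, which encodes the chaperone BiP, was in 2 and 0 libraries. Sterol synthesis genes had 11 and 12 of 23 against 8 and 6, and Insig1 was in 2 and 0. Genes of the NAD and sirtuin pathway had 9 and 8 of 27 in both genotypes, with Nampt and Nmnat2 in 3 knock-in and 2 wild type libraries. Glutamate and GABA receptors had 23 and 20 of 38 against 20 and 16, and Gria2 was in 2 and 0. Housekeeping genes had 15 and 11 of 20 against 12 and 11, with Vcp in 3 libraries of each genotype and Hsp90ab1 in 3 and 2. In the lists of other tissues, Rom1 was in 2 and 1 libraries, Gnat2 in 1 and 0, Mylpf in 3 and 2 and Acta1 in 1 and 0. The peaks of Rom1 also overlapped the window of Eml3, those of Mylpf that of Tbc1d10b, and that of Gnat2 those of Ampd2 and Gm12500. These peaks may therefore belong to the neighbouring genes. Each gene given here as in 2 knock-in and 0 wild type libraries had a conditional exact p of 0.501. Of 7100 genes with a peak in both knock-in replicates 1 and 2, 737 (10.4%) had no peak in wild type replicates 1 and 2.

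None of the 19 lists passed the test between genotypes. Relative to all other genes of the same library, 16 lists had a higher and 3 a lower mean log2 odds in knock-in. As differences in percentage points 9 were higher and 10 lower, within replicates 1 and 2 the log2 odds of 13 were higher and of 6 lower, and without knock-in replicate 4 those of 7 were higher and of 12 lower. The largest difference was 0.85 for SAGA and ATAC subunits, with an exact permutation p of 0.4. It was -0.015 within replicates 1 and 2 and 1.71 within replicates 3 and 4, and 0.37 without wild type replicate 4. The smallest exact permutation p was 0.171, for glutamate and GABA receptors, whose difference was -0.54, with 0.013 within replicates 1 and 2. It was -0.29 without wild type replicate 4 and -0.72 without wild type replicate 2, where the exact permutation p was 0.0286 and the adjusted p 0.543. With all libraries, all adjusted p were 0.971. These odds set each list against the other genes of the same library, whereas the counts of members do not. Where a list had no member with a peak, its odds came only from the 0.5 added and the other genes. That held for astrocyte, oligodendrocyte, microglia and photoreceptor lists in replicates 3 and 4, and for some libraries of other lists. Among these were wild type replicate 4 for SAGA and ATAC subunits and knock-in replicate 4 for glutamate and GABA receptors. The differences of 0.85 and -0.54 therefore rest in part on such values. Without knock-in replicate 4 the difference for receptors was -0.40. Such values also enter the tallies of higher and lower lists.

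**Figure D4:**
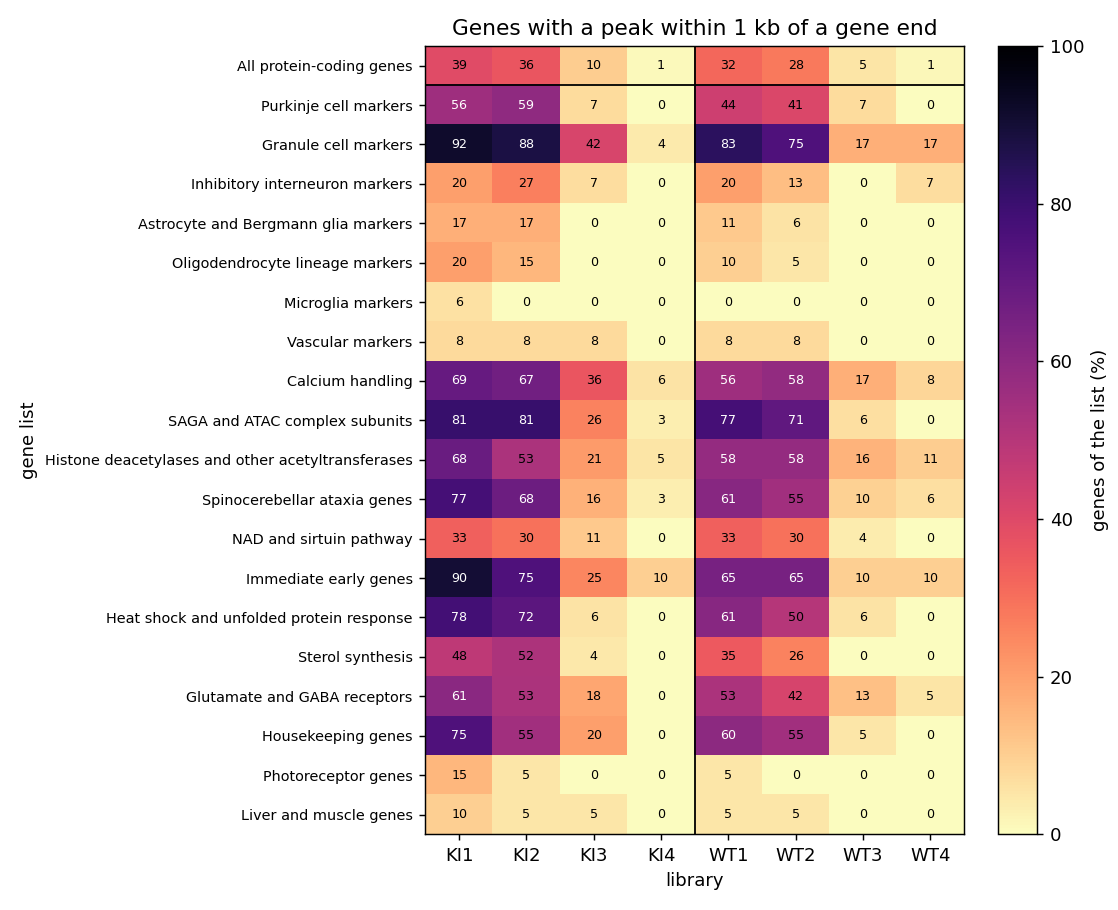
Percent of the genes of each list with a peak within 1 kb of either gene end, in each knock-in (KI) and wild type (WT) library by replicate number, with all protein-coding genes in the top row. Granule cell markers lie between 75 and 91.7% in replicates 1 and 2 of both genotypes, where all genes lie between 27.8 and 39.1%.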

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

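Of the tests in this part, those on list length, on the score of the wild type windows and on other splits of the libraries were chosen after the results were seen, except the splits for gene lists.

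Within a genotype, 4 library values stood apart from the other 3. Knock-in replicate 4 had 158 of its 1266 peaks, 12.5%, on unplaced sequences, against 0.189 to 2.08% in the other knock-in libraries. Wild type replicates 4 and 3 had 10.2 and 4.77%, so high values went with the short lists in both genotypes. Microglia markers had a peak at 5.88% of members in knock-in replicate 1 and at none in the others. Vascular markers had a peak at 0% of members in knock-in replicate 4 and at 7.69% in the other knock-in libraries. Photoreceptor genes had a peak at 5% of members in wild type replicate 1 and at none in the other wild type libraries. In 51 groups tested, chance alone gives about 2.55 such values, and the last 3 rest on at most 1 gene per library.

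The lists of replicates 3 and 4 were shorter and narrower than those of replicates 1 and 2 in both genotypes, with a 95th percentile of width of 295 to 369.5 bp against a 5th percentile of 626 to 699 bp. Weaker enrichment or depth predicts that they keep the strongest peaks, and replicate 3 overlapped 65.5% of the top quartile by score of knock-in replicate 1 and 3.85% of the bottom quartile. In wild type the shares were 39.7% and 4.00%, a ratio of 9.94, so lower enrichment or depth may contribute to the short lists of replicate 3. Replicate 4 overlapped 6.83% and 2.19% of these quartiles in knock-in and 13.3% and 2.77% in wild type. It missed most of the strongest peaks, and so did wild type replicate 3. How far lower enrichment or depth accounts for these lists therefore stays open. Other settings of the peak caller, which are not given in the sources used here, also stay open as untested, and no biological explanation was tested, since the labels give both sets the same age and tissue.

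Among replicates 1 and 2, 737 gene-end windows had a peak in both knock-in libraries and neither wild type library, and 39 the reverse. The knock-in windows held weak peaks, at a median score percentile of 29.9, but the wild type windows did too, at 28.5, so the score does not show why one direction outnumbers the other. Longer knock-in lists alone do not, since lists of 7735 peaks each gave 385 against 71, a ratio of 5.42. Only 237 of the 737 windows were still in both knock-in and neither wild type list at that length. Wild type replicate 1 had the longest of these lists, so equal length took the most peaks from it. Over all genes, however, the knock-in libraries had a peak at 8565 and 7927 genes and the wild type libraries at 6977 and 6076. Equal numbers of peaks do not remove that difference, and the excess of knock-in windows is not separate from it. Of the 3 splits of these 4 libraries, 1, the real one, gave as many windows as the real 776, the next highest being 371, and 3 splits are too few for a share under 0.05. Lower detection of weak peaks in the wild type lists and the genotype itself both stay open.

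Chance could not be excluded for the restricted regions, since 24 of the 35 splits gave as many as the real 79, and the highest other split gave 4482. Among the 18 splits that, like the real one, put 2 libraries of replicates 1 and 2 on each side, 7 gave as many, with up to 125 elsewhere. For called regions, genes and gene lists the real count was 0, which all 35 splits equal or exceed whatever the data, so the splits do not bear on chance there. The real split had 53 regions and 90 genes at an unadjusted conditional exact p under 0.05, and 0 of either by Fisher's exact test. The smallest p by Fisher's exact test was 0.143 for both, since no feature was in all 4 libraries of one genotype alone. Other splits gave up to 13 called regions, 4 called genes and 0 called gene lists. The split of replicates 1 and 2 against replicates 3 and 4 gave the 4482 regions and the 13 called regions, which points to a structure of the samples other than genotype.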

How the results depend on the processing

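Using replicates 1 and 2 only, replicates 3 and 4 only or whole gene bodies was chosen after seeing the data. No comparison between genotypes passed its threshold over all regions, genes or lists under any alternative, except the call of Lrrc74b without wild type replicate 2. Over the alternatives, 128 values of the comparisons kept their direction and side of the threshold or stayed near their count, 22 changed sign and 26 counts moved. For gene lists 255 values kept their direction and 68 changed sign, and of 918 values for named genes 660 kept their direction, 104 had no difference left, 1 changed sign and 153 were of genes with no difference to begin with. Of the 918, 1 newly passed its threshold. Changes of sign are therefore changes of differences that lay within the spread between libraries, and their cause was not tested. Unknown depth limits every count.

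With the replicate number as a block, which cannot give an exact permutation p below 0.125, the difference in peaks per library stayed 1187 (paired exact permutation p = 0.500). Restricted regions were 41 and 51, and 0 regions, genes and lists were called over all of them. Immediate early genes and sterol synthesis genes, with log2 odds differences of 0.69 and 0.65, reached the smallest possible paired exact permutation p of 0.125. Their adjusted p was 0.891. The block ended the call of Kat5 over its list alone (adjusted exact p = 0.464). Correlations of deviations between same-numbered libraries were 0.149, 0.208, 0.201 and 0.411 over merged regions but 0.0464, 0.112, 0.135 and 0.401 over gene-end windows. Not every library correlated best with its own number, so the numbers were not taken to pair the libraries.

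Leaving out one library at a time, the knock-in minus wild type difference ranged from -286 to 3158 for peaks per library, from -0.833 to 4.22 Mb for covered length, from -141 to 230 bp for median peak width and from -5.01 to 15.3 points for the share of peaks at gene ends. The sign changed without knock-in replicate 2 or wild type replicate 4 for all of these, without knock-in replicate 1 for all but peaks per library, and without wild type replicate 3 for covered length and width. Within minus between overlap of the shorter list ranged from -0.836 to 3.18 points. Regions restricted to knock-in ranged from 1 to 119 and to wild type from 0 to 77, under a rule that changed with the library left out. Gene calls ranged from 0 to 1, the call being Lrrc74b without wild type replicate 2. The log2 odds differences of lists ranged from -0.11 to 0.42 for Purkinje markers, -0.18 to 0.47 for granule markers, -0.68 to 0.86 for interneuron markers, -0.64 to 0.78 for astrocyte markers, -0.51 to 0.89 for oligodendrocyte markers, -1.09 to 1.06 for microglia markers, -0.80 to 0.78 for vascular markers -0.034 to 0.51 for calcium handling, 0.37 to 1.28 for SAGA and ATAC subunits and -0.72 to -0.29 for receptors. They ranged from -0.80 to 0.041 for other histone acetylation enzymes, -0.10 to 0.46 for ataxia genes, -0.28 to 0.18 for the NAD pathway, -0.051 to 0.87 for heat shock genes, -0.50 to 1.26 for photoreceptor genes and -0.55 to 0.98 for liver and muscle genes. For immediate early genes the range was 0.33 to 1.10, for sterol synthesis 0.24 to 1.08 and for housekeeping genes 0.13 to 0.54.

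With the 1266 strongest peaks of each library, the overlap difference was -6.45 points, restricted regions were 13 and 14, and lists changed sign to -0.15 for granule markers, 0.039 for interneurons, 0.18 for other histone acetylation enzymes and -0.16 for ataxia genes. The number of peaks has no value at equal length. Reciprocal overlap, which does not apply to the Jaccard index, gave -7.12 points. For regions the rule was instead that the peaks of a library cover a large part of the merged region, and restricted regions were 0 and 0. A restricted region needs a library of replicates 3 or 4, with median peak widths of 132 to 148 bp. The restricted regions had median widths of 1107 and 932 bp, so the 0 and 0 follow largely from peak width. Restricted regions were 0 and 0 when all 4 libraries were required, and 158 and 118 when 1 library of the other genotype was allowed. Windows of 500 bp gave -0.33 for granule markers, 0.37 for interneurons, -0.32 for vascular markers, 0.048 for receptors and -0.12 for liver and muscle genes, and windows of 3 kb gave -0.025 for the NAD pathway. Without a logarithm the differences in percentage points were -0.864 for astrocytes, -0.030 for oligodendrocytes, -3.56 for microglia, -3.11 for vascular markers, -3.18 for the NAD pathway, -1.28 for photoreceptor genes and -2.53 for liver and muscle genes.

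With replicates 1 and 2 only, the Jaccard difference was 0.022 and restricted regions were 898 and 174, since 2 libraries then suffice. Lists gave 0.029 for interneurons, -0.51 for vascular markers, -0.015 for SAGA and ATAC subunits, -0.51 for the NAD pathway, 0.013 for receptors, -0.042 for housekeeping genes and -0.10 for liver and muscle genes. With replicates 3 and 4 only, the width difference was -0.50 bp, the overlap difference -2.11 points and restricted regions 90 and 85. Lists gave -0.15 for Purkinje, astrocyte, oligodendrocyte and microglia markers, heat shock and photoreceptor genes, -0.19 for granule markers and -0.17 for ataxia genes. The astrocyte, oligodendrocyte, microglia and photoreceptor lists had no member with a peak in these libraries. Purkinje and heat shock lists had equal counts in both genotypes. The -0.15 therefore came from the 0.5 added and the other genes, not from a difference between members. Whole gene bodies gave -0.34 for Purkinje markers, -0.00029 for the NAD pathway and a difference of 1 library for Mideas, and Grm8, a name chosen after its values were seen, passed over the receptor list alone (adjusted exact p = 0.0356). At equal length within replicates 1 and 2, windows of one genotype only numbered 385 and 71.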

Other observations

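The pairs of libraries compared in this part, its list comparisons and the genes named for width or position were chosen after seeing the data. The score-matched width test was set before its result was seen.

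Granule cell markers held broad gene-end peaks. Widths of windows in this paragraph are geometric means, over the 4 libraries of replicates 1 and 2, of the widest peak in the window. Over the 5008 windows with a peak in all 4 of these libraries, the median of this width was 1367 bp. The widest were at predicted genes on chromosome 6, led by Gm40365 and Gm40367 at 17522 bp, which lie in one merged region with Rn4.5s. Zic2 reached 5504 bp, Zic1 and Zic4, which share one peak, 5012 bp, Uncx 4641 bp and Grm4 3905 bp. Of 11 lists with enough members, granule cell markers had the highest median width rank, at the 97.6th percentile of windows with a median of 2739 bp over 17 genes. Glutamate and GABA receptors followed with 1930.5 bp over 15 genes, and housekeeping genes were at 1309 bp over 8 genes. Stronger peaks are wider, but the granule list lay at percentile 100 of 10000 random lists matched on peak score, against 99.7 for glutamate and GABA receptors, 94.6 for immediate early genes and 94.0 for Purkinje cell markers. Peak strength alone therefore does not account for the granule width, and how far the abundance of granule cells or the closeness of neighbouring genes may do so was not tested.

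The share of knock-in windows missing from both wild type libraries of replicates 1 and 2 was tied to peak strength. It was 37.6% in the lowest quintile of windows by score, then 11.3, 2.04 and 0.634% in the next quintiles and 0.282% in the highest. Of 18 lists with members in both knock-in libraries, calcium handling genes had 4 of the 23 members with a peak in both knock-in libraries in this class, against 1.42 expected for genes of matched score. The one-sided permutation p was 0.0204 and the adjusted p 0.367. Without matching 2.39 were expected, with a one-sided exact hypergeometric p of 0.211 and an adjusted p of 0.949. Gria2 was in the class with strong peaks, at score percentiles 75.1 and 89.8 in the knock-in lists.

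The widest merged region lay on chromosome 9 from 2999743 to 3038669, over Mir101c, with a peak in all 4 wild type libraries and in knock-in replicate 4. In each of these libraries it was 1 peak of 38424 to 38927 bp with the same score of 3100, also in short lists of narrow peaks. Whether it reflects acetylation was not tested, and no difference between genotypes is read from it. The next widest lay on chromosome 6 from 47736832 to 47773807 and from 47650303 to 47687238, the latter over Rn4.5s, with peaks in 7 and 8 libraries.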
